A study of Mus musculus with 15 samples.

How the data were processed

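RNA-seq libraries of purified dermal adipocytes were compared. The adipocytes came from dorsal skin of C57BL/6 mice at P21, P25, P29, P35 and P49, with 3 libraries per age, and had been separated by enzyme digestion and floating centrifugation. The deposited file gave FPKM for 35275 genes in each of the 15 libraries, 10482 of them at 0 in all libraries. Per the submitters' processing notes, reads were handled with CASAVA and FastQC, aligned with STAR 2.5 and counted with HTSeq 0.6.1 on mm10/GRCm38. The annotation release was not given in the sources used here. In each library FPKM times the gene length was a whole multiple of 1 step, to within 0.05 read for 100% of genes. The reads counted to genes could therefore be recovered, 23214103 to 32219574 per library. At the lowest and highest depth, 3 reads on a gene of 1 kb corresponded to 0.129 and 0.0931 FPKM.

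Genes at 1 FPKM or more in at least 3 libraries were tested, 12259 in all. Log2 of FPKM + 1 was fitted with limma 3.58.1 (statmod 1.5.0) in R 4.3.3, with 1 mean per age over all 15 libraries and a trended, robust empirical Bayes step. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. Comparisons were each age against the one before, P49 against P21, and 1 test over the 5 ages. The test, the comparisons, the gene lists and the rule for naming genes were chosen before the data were examined. A test on counts had been planned, with this test on log2 values as the stated fallback for a file of normalized values. The labels give no animal, litter or day that same-numbered libraries share. Of 30 same-numbered pairs 15 correlated above 0.1 in their deviations from the age means. All 3 pairs did for P25 with P29 and for P29 with P35, so for these comparisons the count and calls with the number as a block are given where they differ.

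Named genes were, per comparison, the 10 largest rises and 10 largest falls among genes past the threshold with at least 5 FPKM in the higher age, no overlap between the libraries of the 2 ages and an established symbol. Where fewer than 3 genes passed, the 5 of the smallest p were named. Members of fixed lists were named as the 2 largest called changes per direction, beside a short fixed set of cell markers. Of 37 fixed lists with 615 genes, 612 genes were in the file and 510 were tested, and 36 lists had at least 3 tested genes. Krt85, Trdc and Ca9 were not matched, and Gpat3, Gpat4 and Adgre1 were matched by gene ID. Lists were tested with camera at a preset correlation of 0.01, adjusted over 180 tests, and counts of members were also adjusted over the list alone. Principal components used the 500 most variable genes.

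Alternatives planned were quantile normalization, no trend, no filter, a pseudocount of 0.1, the replicate number as a block, only the 2 ages compared, a 2-fold minimum, fry, an estimated correlation, lists without shared members, and leaving out each library in turn. Median-ratio scaling, the stromal index as a covariate, library weights and voom on the recovered reads were added after the data were seen. The test was tried on simulated data: of 100 genes changed 2-fold 59% were recovered and of 100 changed 4-fold 84%, with 13 false calls among 12177 genes. The simulation drew each gene independently, without deviations shared by the genes of a library. It therefore gives no rate of false calls for libraries that deviate as a whole. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.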

Results

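Adipocyte transcripts were abundant in all 15 libraries. Adipoq, which encodes adiponectin, averaged 2040 ± 313, 2214 ± 700.2, 3126 ± 135, 2635 ± 121, 2491 ± 59.2 FPKM at P21, P25, P29, P35 and P49 (mean ± SD, n = 3 here and below). Plin1, the lipid droplet coat protein, averaged 745 ± 59.6, 1083 ± 352, 1274 ± 106, 1260.3 ± 77.5, 1318 ± 71.5 FPKM at the same ages. Xist reached at most 0.0217 FPKM in any library and the Y-linked Ddx3y averaged 26.8 ± 1.04, 23.1 ± 2.03, 24.4 ± 0.922, 22.1 ± 1.03, 24.3 ± 0.852 FPKM, the pattern of male animals. RNA of other cells was present too. Pecam1, an endothelial gene, stood at 47.3 ± 18.5, 19.99 ± 18.1, 15.2 ± 8.13, 15.3 ± 3.23, 11.4 ± 1.58 FPKM, and Col1a1, a fibroblast collagen, at 2337 ± 582, 2159.9 ± 2601, 527 ± 218, 534 ± 253, 381 ± 186 FPKM.

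The first principal component of the 500 most variable genes held 67.7% of the variance, and the second 12.5%. On these 2 components P25 replicate 2 lay among the P21 libraries, with its highest correlation to P21 replicate 1 (r = 0.971) and a mean r of 0.926 to the other P25 libraries. It was still apart from P21 in other ways. On the third component P25 replicate 2 lay at -15.5, against 5.94 to 7.87 at P21. Its mean r to the P21 libraries was 0.965, where these correlated with each other at 0.984 to 0.987. By the stromal index, though, P25 replicate 2 lay within the range of the P21 libraries. For P25 replicate 2 this index, the mean log2 value of the endothelial, nerve and lymphocyte lists, was 3.66, against 2.32 and 2.20 in P25 replicates 1 and 3 and 3.22 to 3.96 at P21. P29 replicate 2 (2.95) and P35 replicate 2 (2.76) were next highest. The labels do not say whether replicates are separate animals or pools, so the p-values below measure the spread between these samples, which may be technical.

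**Figure D1:**
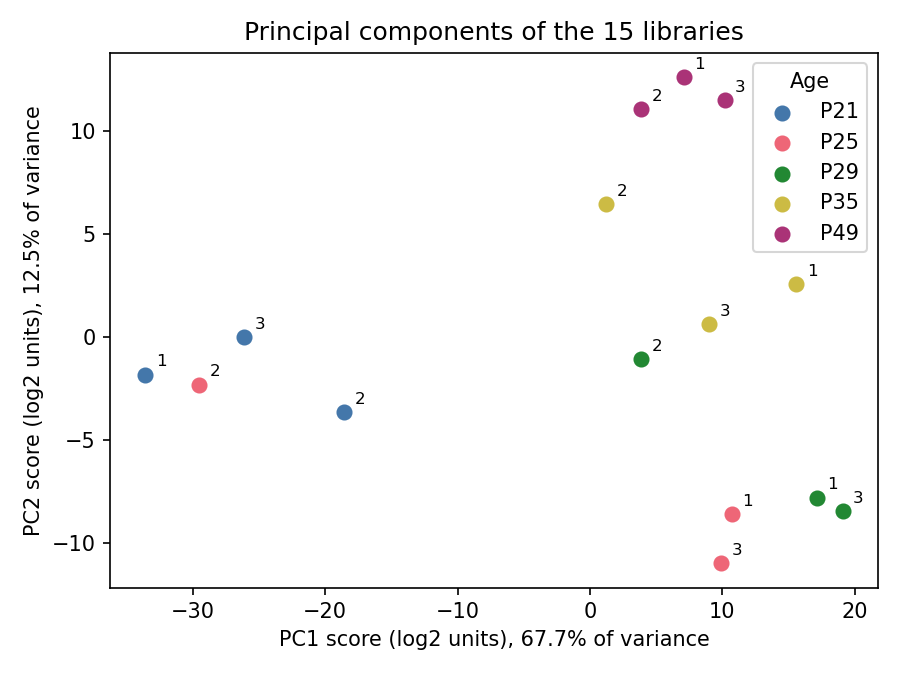
Principal components of the 15 libraries, from log2 of FPKM + 1 of the 500 most variable genes. Numbers mark the replicate.

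Across the 5 ages, 3224 of 12259 genes differed, and 5416 had an unadjusted p under 0.05. P21 was the age of the highest mean for 1489 of these genes, P25 for 490, P29 for 384, P35 for 345 and P49 for 516. Without P25 replicate 2, an alternative read this way only after the data were seen, 6378 genes differed and 3192 of the 3224 were kept. Without P21 replicate 1 the count was 1417, and with library weights 7383. The 36 fixed lists gave 180 list tests over the 5 comparisons, of which 75 passed by camera. With an estimated correlation camera passed 0, and the rotation test fry passed 17 of the same tests. Test direction, median and mean differed in sign in 14 list tests, none of them past the threshold: melanocyte for P25 against P21, P49 against P35 and P49 against P21, clock genes for P29 against P25, fatty acid synthesis, extracellular matrix, hair cycle signals and Wnt targets for P35 against P29, preadipocyte, myofibroblast, lymphocyte and hypoxia genes for P49 against P35, and thermogenic and hair shaft genes for P49 against P21.

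**Figure D2:**
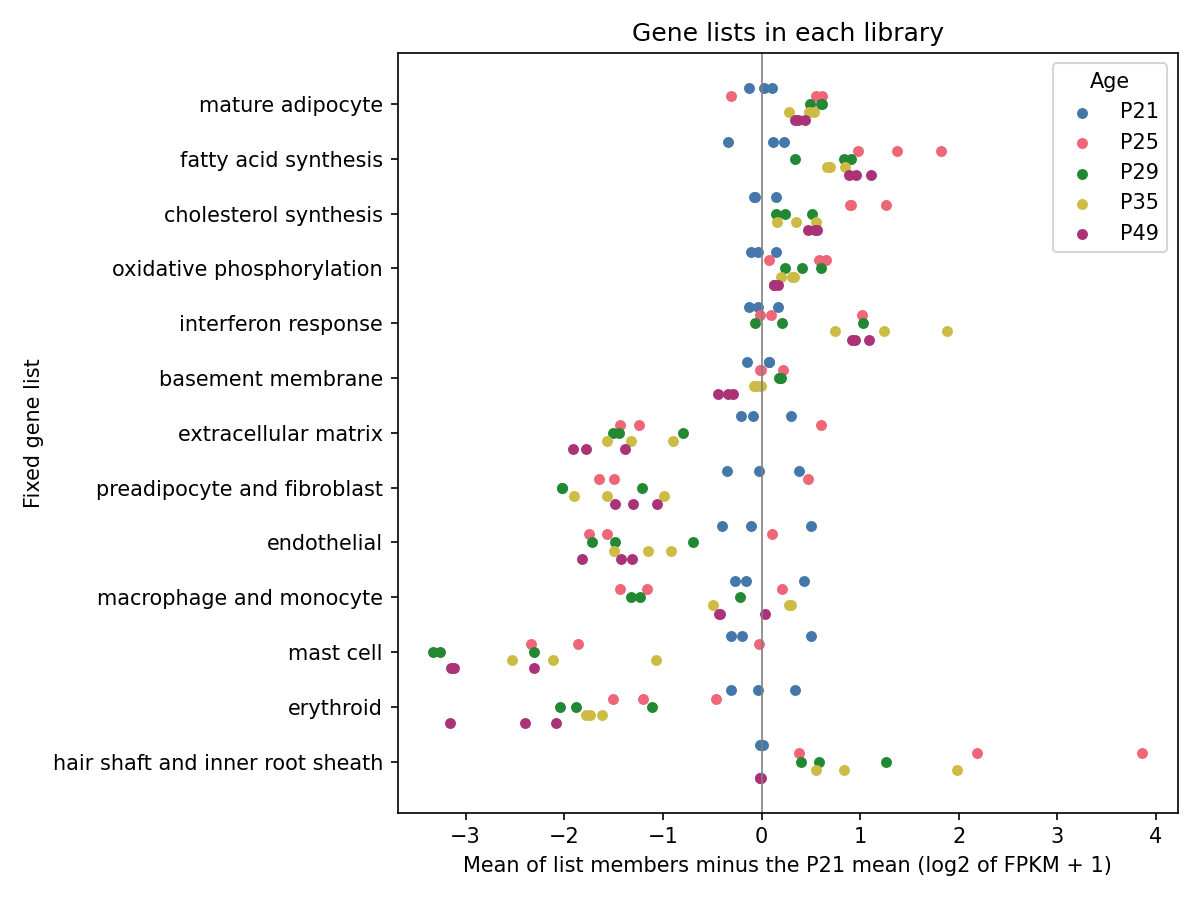
Mean of a selected part of the fixed gene lists in each library, relative to the mean of the P21 libraries. Each point is 1 library.

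Between P21 and P25 Me1, Acly and Elovl6, genes of fatty acid synthesis, were among the largest rises, and Igfbp3 and H19 among the largest falls. Me1 (ENSMUSG00000032418, chromosome 9, 86581371 to 86695953, GRCm38), which makes NADPH for lipid synthesis, rose from 75.2 ± 26.1 to 401 ± 118 FPKM (log2 2.43, adjusted p = 0.00102). Acly, which makes cytosolic acetyl-CoA, rose from 94.5 ± 40.9 to 478 ± 178 FPKM (log2 2.38, adjusted p = 0.00304). Acss2 rose from 17.5 ± 7.36 to 94.3 ± 43.6 FPKM (log2 2.36, adjusted p = 0.00224). Elovl6 rose from 3.46 ± 1.11 to 19.9 ± 5.37 FPKM (log2 2.23, adjusted p = 0.0021). Scd2 rose from 14.7 ± 4.996 to 71.4 ± 22.6 FPKM (log2 2.21, adjusted p = 0.00135). The lipid carrier Fabp5 rose from 27.03 ± 6.84 to 130 ± 23.8 FPKM (log2 2.24, adjusted p = 0.000509). The glycogen-targeting subunit Ppp1r3b rose from 1.89 ± 0.629 to 14.2 ± 6.42 FPKM (log2 2.31, adjusted p = 0.00388). Igfbp3 (ENSMUSG00000020427, chromosome 11, 7206086 to 7213923, GRCm38), which binds insulin-like growth factors, fell from 215 ± 72.5 to 30.5 ± 22.2 FPKM (log2 -2.94, adjusted p = 0.00104). The imprinted RNA H19 fell from 45.7 ± 16.1 to 8.61 ± 8.33 FPKM (log2 -2.55, adjusted p = 0.00556). The matrix gene Thbs2 fell from 138 ± 17.4 to 32.5 ± 13.99 FPKM (log2 -2.14, adjusted p = 0.00064). Mmp11 fell from 12.7 ± 7.75 to 1.18 ± 0.874 FPKM (log2 -2.56, adjusted p = 0.00141). The retinoic acid hydroxylase Cyp26b1 fell from 10.7 ± 8.07 to 1.14 ± 1.12 FPKM (log2 -2.36, adjusted p = 0.00308). Fam150b fell from 22.5 ± 14.2 to 3.96 ± 2.24 FPKM (log2 -2.17, adjusted p = 0.00351). Fmo2 fell from 16.99 ± 8.56 to 3.79 ± 3.53 FPKM (log2 -2.06, adjusted p = 0.00771). Mdk fell from 12.1 ± 4.49 to 2.65 ± 2.71 FPKM (log2 -2.03, adjusted p = 0.00747).

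The hair genes Krt71 and Krt25 had the largest rises, but from uneven libraries. Krt71 rose from 0.0499 ± 0.0136 to 19.5 ± 23.7 FPKM (log2 3.32, adjusted p = 0.0205, but 0.0768 without P25 replicate 3, the highest of 3 libraries whose absence ended the call). Krt25 rose from 0.0128 ± 0.0111 to 13.3 ± 16.2 FPKM (log2 2.93, adjusted p = 0.0242, but 0.0862 without P25 replicate 3, the highest of 4 such libraries). Krt25 was at 0.631 FPKM in P25 replicate 1, 31.6 in replicate 2 and 7.63 in replicate 3. Mgp fell from 38.4 ± 26.0 to 7.22 ± 7.28 FPKM (log2 -2.43, adjusted p = 0.014, but 0.0706 without P25 replicate 3, the highest of 2 such libraries). Hmcn2 fell from 29.2 ± 10.8 to 6.68 ± 7.36 FPKM (log2 -2.32, adjusted p = 0.00965, but 0.0514 without P25 replicate 3). Orm1, an acute phase gene with near-identical copies that make its level uncertain, rose from 31.2 ± 18.4 to 175 ± 55.5 FPKM (log2 2.64, adjusted p = 0.00185).

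The list of fatty acid synthesis rose: 12 up of 17 genes, and 14 up adjusted over the list alone. For fatty acid synthesis genes camera gave adjusted p = 5.8e-12, adjusted p = 0.591 with an estimated correlation. Its count was 16 up without P25 replicate 2. Cholesterol synthesis rose: 18 up of 22 genes, and 18 up adjusted over the list alone. For cholesterol synthesis genes camera gave adjusted p = 1.1e-15, adjusted p = 0.314 with an estimated correlation. Insig1 (from 59.7 ± 12.01 to 268 ± 54.5 FPKM, log2 2.15) and Mvd (from 4.12 ± 0.785 to 17.98 ± 7.20 FPKM, log2 1.84) led the list. Triglyceride synthesis rose: 6 up of 11 genes, and 6 up and 2 down adjusted over the list alone. For triglyceride synthesis genes camera gave adjusted p = 0.000547, adjusted p = 0.844 with an estimated correlation. Agpat2 (from 144 ± 28.8 to 537 ± 157 FPKM, log2 1.87) and Dgat2 (from 268 ± 35.7 to 952 ± 263 FPKM, log2 1.79) led the list. Oxidative phosphorylation rose: 12 up of 30 genes, and 21 up adjusted over the list alone. For oxidative phosphorylation genes camera gave adjusted p = 3.2e-11, adjusted p = 0.844 with an estimated correlation. Its count was 30 up without P25 replicate 2. The mature adipocyte list rose: 6 up and 2 down of 23 genes, and 8 up and 2 down adjusted over the list alone. For mature adipocyte genes camera gave adjusted p = 0.00317, adjusted p = 0.844 with an estimated correlation, ended without P25 replicate 1 at 0.0653, and with quantile normalization at 0.116. Members included Tusc5 (from 56.8 ± 9.40 to 118 ± 26.2 FPKM, log2 1.03) up and Cidec (from 2462 ± 566 to 1473 ± 574 FPKM, log2 -0.80) down. Hypoxia and glycolysis rose: 8 up and 3 down of 16 genes, and 8 up and 3 down adjusted over the list alone. For hypoxia and glycolysis genes camera gave adjusted p = 0.0132, adjusted p = 0.844 with an estimated correlation, ended with quantile normalization at 0.0874. Members included Gapdh (from 408 ± 99.4 to 896 ± 131 FPKM, log2 1.16) up and Adm (from 85.1 ± 19.4 to 32.8 ± 20.1 FPKM, log2 -1.48) down. With the stromal index as a covariate, triglyceride synthesis (adjusted p = 0.0972) and hypoxia and glycolysis (0.0697) no longer passed, and the mature adipocyte list turned to down without passing (0.696).

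Fatty acid oxidation rose weakly: 1 up of 18 genes, and 1 up adjusted over the list alone. For fatty acid oxidation genes camera gave adjusted p = 0.0485, adjusted p = 0.844 with an estimated correlation, ended without each of 10 single libraries: P25 replicate 1 0.383, P25 replicate 3 0.256, P21 replicate 1 0.13, P21 replicate 3 0.0843, P29 replicate 3 0.0535, P49 replicate 3 0.0525, P35 replicate 3 0.0509, P35 replicate 2 0.0507, P49 replicate 2 0.0507, P49 replicate 1 0.0504, and with quantile normalization at 0.262 and median-ratio scaling at 0.0563. Lipolysis genes went both ways: 2 up and 2 down of 16 genes, and 2 up and 3 down adjusted over the list alone. For lipolysis genes camera gave adjusted p = 0.402. Members included Prkaca (from 74.4 ± 7.56 to 125 ± 31.3 FPKM, log2 0.71) up. Insulin and glucose genes did not pass: 3 down of 16 genes, and 1 up and 3 down adjusted over the list alone. For insulin and glucose handling genes camera gave adjusted p = 0.713. Pdk4 (from 73.9 ± 16.1 to 28.1 ± 6.64 FPKM, log2 -1.37) fell. Clock genes did not pass as a list: 3 up and 2 down of 17 genes, and 3 up and 4 down adjusted over the list alone. For circadian clock genes camera gave adjusted p = 0.684. Dbp (from 24.9 ± 0.263 to 80.4 ± 11.01 FPKM, log2 1.65) rose, and the time of harvest is not labelled. Hair cycle signals did not pass: 2 up and 4 down of 24 genes, and 2 up and 6 down adjusted over the list alone. For secreted hair cycle signals camera gave adjusted p = 0.183. Members included Igf1 (from 51.4 ± 7.78 to 82.2 ± 20.1 FPKM, log2 0.64) up and Dkk3 (from 6.77 ± 3.76 to 1.51 ± 1.76 FPKM, log2 -1.73) down. Extracellular matrix did not pass either: 1 up and 2 down of 26 genes, and 1 up and 2 down adjusted over the list alone. For extracellular matrix genes camera gave adjusted p = 0.114. Members included Col5a3 (from 107 ± 31.03 to 236 ± 30.7 FPKM, log2 1.17) up and Lox (from 71.4 ± 3.13 to 35.3 ± 20.8 FPKM, log2 -1.14) down. Its count was 1 up and 21 down without P25 replicate 2. Under the stromal covariate fatty acid oxidation turned to down without passing (adjusted p = 0.152).

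Several lists of other cells fell over the same interval, and others did not. The endothelial list fell: 1 down of 15 genes, and 0 adjusted over the list alone. For endothelial genes camera gave adjusted p = 0.00307, adjusted p = 0.844 with an estimated correlation. Members included Cldn5 (from 52.8 ± 21.3 to 16.9 ± 18.1 FPKM, log2 -1.99). The endothelial count was 15 down without P25 replicate 2. Macrophage and monocyte genes fell: 1 down of 18 genes, and 1 down adjusted over the list alone. For macrophage and monocyte genes camera gave adjusted p = 0.0181, adjusted p = 0.844 with an estimated correlation, ended without P25 replicate 1 at 0.131 and P25 replicate 3 at 0.119 and P21 replicate 3 at 0.0711. Members included Cd163 (from 95.8 ± 25.001 to 32.1 ± 22.2 FPKM, log2 -1.73). Mast cell genes fell: 1 down of 7 genes, and 1 down adjusted over the list alone. For mast cell genes camera gave adjusted p = 0.0237, adjusted p = 0.844 with an estimated correlation, ended without P25 replicate 1 at 0.129. Members included Kit (from 5.28 ± 1.67 to 1.83 ± 1.55 FPKM, log2 -1.25). Preadipocyte and fibroblast genes fell as a list: 0 of 17 genes, and 0 adjusted over the list alone. For preadipocyte and fibroblast genes camera gave adjusted p = 0.0308, adjusted p = 0.844 with an estimated correlation, ended without P25 replicate 1 at 0.277 and P21 replicate 1 at 0.144 and P25 replicate 3 at 0.092. Skeletal muscle fell: 0 of 12 genes, and 8 down adjusted over the list alone. For skeletal muscle genes camera gave adjusted p = 0.0149, adjusted p = 0.844 with an estimated correlation, ended without P21 replicate 1 at 0.31 and P25 replicate 1 at 0.0618. Erythroid genes fell: 2 down of 5 genes, and 5 down adjusted over the list alone. For erythroid genes camera gave adjusted p = 0.0189, adjusted p = 0.844 with an estimated correlation. Immediate early genes, which respond to tissue handling, fell: 12 down of 19 genes, and 16 down adjusted over the list alone. For immediate early and dissociation genes camera gave adjusted p = 1.3e-05, adjusted p = 0.844 with an estimated correlation. Klf4 (from 180.3 ± 27.7 to 67.2 ± 52.1 FPKM, log2 -1.66) and Junb (from 629 ± 58.3 to 284 ± 196 FPKM, log2 -1.35) led the list. Hair shaft genes rose: 3 up of 7 genes, and 7 up adjusted over the list alone. For hair shaft and inner root sheath genes camera gave adjusted p = 0.000348, adjusted p = 0.844 with an estimated correlation, ended without P25 replicate 2 at 0.0506. Interferon genes rose: 0 of 19 genes, and 0 adjusted over the list alone. For interferon response genes camera gave adjusted p = 0.0302, adjusted p = 0.844 with an estimated correlation, ended without P25 replicate 2 at 0.605 and P21 replicate 2 at 0.0762, and with median-ratio scaling at 0.075. The lists of pericytes (adjusted p = 0.477), nerve (0.882), melanocytes (0.63), lymphocytes (0.125), keratinocytes (0.19) and dermal papilla (0.633) did not pass. In these, Cspg4 (from 9.96 ± 2.22 to 33.2 ± 6.47 FPKM, log2 1.64), Pmp22 (from 144 ± 15.1 to 264 ± 10.6 FPKM, log2 0.87) and Dct (from 0.672 ± 0.177 to 2.60 ± 1.13 FPKM, log2 1.06) rose, unlike the means of their lists. The pericyte list had a mean log2 of 3.19 ± 0.352 at P21 and 2.72 ± 0.906 at P25. The nerve list had 3.20 ± 0.409 and 2.82 ± 0.438, and the melanocyte list 2.10 ± 0.115 and 2.06 ± 0.464. Under the stromal covariate the endothelial (adjusted p = 0.909), mast cell (0.482), skeletal muscle (0.419) and erythroid (0.183) lists no longer passed, and the macrophage (0.645) and preadipocyte (0.253) lists turned to up without passing.

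In all, 2312 genes passed between P21 and P25 by limma, 1027 up and 1285 down, and 351 of these changed at least 2-fold. Without P25 replicate 2 the count was 5545, with 2226 of the 2312 kept, and without P25 replicate 3 it was 810. With P21 and P25 alone in the fit 0 genes passed by limma, against 4341 at an unadjusted p under 0.05 in the fit of all ages and 2373 by voom. Library weights gave 5924, and by voom Krt71 and Krt25 did not pass (adjusted p = 0.194 and 0.171). The direction of the split depended on scaling: quantile normalization gave 1423 up and 861 down, and median-ratio scaling 1429 up and 935 down. Quantile normalization moved the median of all genes by 0.102 on the log2 scale.

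From P25 to P29 the sterol synthesis genes Sqle, Msmo1 and Idi1 were among the largest falls, and Pmepa1, Synpo2 and some Mup genes among the largest rises. Pmepa1 (ENSMUSG00000038400, chromosome 2, 173224458 to 173276533, GRCm38), a brake on TGF-beta signalling, rose from 28.5 ± 1.65 to 81.3 ± 18.9 FPKM (log2 1.45, adjusted p = 0.00413). The actin-binding gene Synpo2 rose from 10.9 ± 1.10 to 31.1 ± 5.97 FPKM (log2 1.42, adjusted p = 0.00579). The pantetheinase Vnn1 rose from 5.08 ± 2.13 to 21.9 ± 6.13 FPKM (log2 1.94, adjusted p = 0.0287, but 0.151 without P29 replicate 2, the highest of 6 such libraries). The secreted Lrg1 rose from 351 ± 101 to 836 ± 172 FPKM (log2 1.27, adjusted p = 0.0397, but 0.192 without P29 replicate 2, the highest of 12 such libraries). The proton channel Hvcn1 fell from 8.03 ± 1.12 to 3.32 ± 0.102 FPKM (log2 -1.05, adjusted p = 0.00413). Sqle, a sterol synthesis enzyme, fell from 6.19 ± 1.04 to 2.28 ± 0.545 FPKM (log2 -1.13, adjusted p = 0.0257, but 0.151 without P29 replicate 2, the highest of 4 such libraries). Msmo1 fell from 14.8 ± 2.498 to 6.75 ± 1.16 FPKM (log2 -1.03, adjusted p = 0.0118, but 0.0893 without P29 replicate 2, the highest of 3 such libraries). Idi1 fell from 7.51 ± 1.18 to 3.68 ± 0.563 FPKM (log2 -0.86, adjusted p = 0.0197, but 0.146 without P29 replicate 2, the highest of 3 such libraries). The desaturase Fads1 fell from 28.3 ± 5.99 to 12.8 ± 1.504 FPKM (log2 -1.08, adjusted p = 0.00592, but 0.051 without P29 replicate 2). Lacc1 fell from 12.01 ± 1.62 to 6.38 ± 0.718 FPKM (log2 -0.82, adjusted p = 0.0485, but 0.225 without P29 replicate 3, the highest of 12 such libraries). Unc5a fell from 17.5 ± 3.75 to 9.61 ± 1.15 FPKM (log2 -0.79, adjusted p = 0.03, but 0.156 without P29 replicate 2, the highest of 8 such libraries). Avpi1 fell from 12.5 ± 2.27 to 7.24 ± 0.200 FPKM (log2 -0.70, adjusted p = 0.03, but 0.151 without P29 replicate 2, the highest of 7 such libraries). Pcsk6 fell from 12.3 ± 1.55 to 7.39 ± 0.826 FPKM (log2 -0.66, adjusted p = 0.0263, but 0.151 without P29 replicate 2, the highest of 3 such libraries). Ran fell from 60.4 ± 3.30 to 44.7 ± 3.64 FPKM (log2 -0.43, adjusted p = 0.04998, but 0.229 without P29 replicate 3, the highest of 15 such libraries).

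Of 8 tested genes for major urinary proteins 5 rose, though their near-identical copies make single levels uncertain. Mup17 rose from 1.10 ± 0.322 to 9.28 ± 0.996 FPKM (log2 2.30, adjusted p = 0.00355). Mup7 rose from 2.99 ± 0.719 to 19.5 ± 4.22 FPKM (log2 2.36, adjusted p = 0.00702, but 0.0583 without P29 replicate 2). Mup15 rose from 2.02 ± 0.472 to 13.2 ± 2.43 FPKM (log2 2.23, adjusted p = 0.00853, but 0.0649 without P29 replicate 2). Mup20 rose from 1.31 ± 0.369 to 6.20 ± 1.41 FPKM (log2 1.64, adjusted p = 0.00413). Mup10 rose from 1.69 ± 0.347 to 6.45 ± 0.876 FPKM (log2 1.47, adjusted p = 0.00948, but 0.071 without P29 replicate 2). Orm2 rose from 3.33 ± 0.752 to 8.996 ± 0.465 FPKM (log2 1.22, adjusted p = 0.0392, but 0.165 without P29 replicate 2, the highest of 10 such libraries). Cholesterol synthesis fell: 4 down of 22 genes, and 20 down adjusted over the list alone. For cholesterol synthesis genes camera gave adjusted p = 2.9e-17, adjusted p = 0.314 with an estimated correlation. Its count was 7 down without P25 replicate 2. Fatty acid synthesis fell: 1 down of 17 genes, and 9 down adjusted over the list alone. For fatty acid synthesis genes camera gave adjusted p = 4.9e-06, adjusted p = 0.844 with an estimated correlation. Basement membrane rose: 1 up of 12 genes, and 5 up adjusted over the list alone. For basement membrane genes camera gave adjusted p = 0.000875, adjusted p = 0.772 with an estimated correlation. Members included Col4a1 (from 525 ± 38.4 to 813 ± 47.3 FPKM, log2 0.63). Insulin and glucose genes rose: 0 of 16 genes, and 1 up adjusted over the list alone. For insulin and glucose handling genes camera gave adjusted p = 0.0006, adjusted p = 0.844 with an estimated correlation. Mast cell genes fell: 0 of 7 genes, and 7 down adjusted over the list alone. For mast cell genes camera gave adjusted p = 6.5e-05, adjusted p = 0.844 with an estimated correlation.

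Other list calls of this interval rested on P25 replicate 2. Mature adipocyte genes rose: 1 up of 23 genes, and 1 up adjusted over the list alone. For mature adipocyte genes camera gave adjusted p = 2.7e-05, adjusted p = 0.844 with an estimated correlation, ended without P25 replicate 2 at 0.592. Members included Tusc5 (from 118 ± 26.2 to 218 ± 2.32 FPKM, log2 0.91). Lipolysis rose: 0 of 16 genes, and 0 adjusted over the list alone. For lipolysis genes camera gave adjusted p = 0.0109, adjusted p = 0.844 with an estimated correlation, ended without P25 replicate 2 at 0.535, and with lists without shared members at 0.088. Fatty acid oxidation rose: 0 of 18 genes, and 1 up adjusted over the list alone. For fatty acid oxidation genes camera gave adjusted p = 8.7e-06, adjusted p = 0.844 with an estimated correlation, ended without P25 replicate 2 at 0.139. Preadipocyte and fibroblast genes fell: 0 of 17 genes, and 0 adjusted over the list alone. For preadipocyte and fibroblast genes camera gave adjusted p = 0.00729, adjusted p = 0.844 with an estimated correlation, ended without P25 replicate 2 at 0.696. Cell proliferation fell: 0 of 21 genes, and 1 down adjusted over the list alone. For cell proliferation genes camera gave adjusted p = 1.2e-06, adjusted p = 0.844 with an estimated correlation, ended without P25 replicate 2 at 0.0596. Keratinocyte genes fell: 0 of 10 genes, and 0 adjusted over the list alone. For epidermal keratinocyte genes camera gave adjusted p = 0.0132, adjusted p = 0.844 with an estimated correlation, ended without P25 replicate 2 at 0.592. Hair shaft genes fell: 0 of 7 genes, and 0 adjusted over the list alone. For hair shaft and inner root sheath genes camera gave adjusted p = 0.00226, adjusted p = 0.844 with an estimated correlation, ended without P25 replicate 2 at 0.197 and P25 replicate 3 at 0.061. Erythroid genes fell: 0 of 5 genes, and 0 adjusted over the list alone. For erythroid genes camera gave adjusted p = 0.0404, adjusted p = 0.844 with an estimated correlation, ended without each of 5 single libraries: P25 replicate 2 0.307, P29 replicate 1 0.112, P29 replicate 3 0.102, P25 replicate 1 0.0653, P35 replicate 2 0.0507, and with no filter at 0.123. Extracellular matrix fell: 0 of 26 genes, and 0 adjusted over the list alone. For extracellular matrix genes camera gave adjusted p = 0.0404, adjusted p = 0.844 with an estimated correlation, ended or turned without each of 5 single libraries: P29 replicate 3 0.141, P29 replicate 1 0.116, P21 replicate 2 0.0537, P21 replicate 3 0.0524, P25 replicate 2 0.0336 in the other direction as higher. Immediate early genes fell: 0 of 19 genes, and 0 adjusted over the list alone. For immediate early and dissociation genes camera gave adjusted p = 0.0404, adjusted p = 0.844 with an estimated correlation, ended or turned without each of 4 single libraries: P29 replicate 1 0.173, P29 replicate 3 0.124, P21 replicate 2 0.05, P25 replicate 2 0.00122 in the other direction as higher. Under the stromal covariate the erythroid (adjusted p = 0.058), extracellular matrix (0.0972) and immediate early (0.539) lists no longer passed.

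In all, 49 genes passed between P25 and P29, 31 up and 18 down, and 1488 had an unadjusted p under 0.05. Quantile normalization gave 28 up and 7 down, voom 20 up and 9 down, and the replicate number as a block 24 up and 7 down. No filter gave 27 genes, the stromal covariate 294, library weights 154 and only the 2 ages 3. Of the 20 named genes, 10 lost their call by voom, 8 with no filter, 4 with quantile normalization and 18 with only the 2 ages. With the block, Vnn1, Lrg1 and Unc5a (adjusted p = 0.0598 each), Avpi1 (0.0663), Ran (0.0774) and Lacc1 (0.0796) did not pass. The count was 77 without P25 replicate 2, with 37 of the 49 kept. Without P29 replicate 2 it was 8, and 15 of the 20 genes named by the rule lost their call. Mup17, Mup20, Pmepa1, Synpo2 and Hvcn1 kept theirs without each library in turn.

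From P29 to P35 no gene passed the test. The genes of the smallest p, none past the threshold, were Comp, a cartilage matrix gene, (0.578 ± 0.0896 to 1.60 ± 0.262 FPKM, log2 0.72, adjusted p = 0.269), the laminin receptor Itga6 (35.1 ± 0.692 to 24.1 ± 1.63 FPKM, log2 -0.53, adjusted p = 0.269), Adam12 (14.5 ± 1.62 to 7.85 ± 0.843 FPKM, log2 -0.81, adjusted p = 0.368), Efcab8 (1.20 ± 0.278 to 2.56 ± 0.149 FPKM, log2 0.70, adjusted p = 0.368) and the laminin chain Lamb1 (90.4 ± 7.99 to 63.6 ± 3.96 FPKM, log2 -0.50, adjusted p = 0.491). Limma called 0 genes, with 812 at an unadjusted p under 0.05, 0 by voom and 2 with no filter. With the stromal covariate 30 genes passed, 23 up and 7 down, the 5 named here among them (adjusted p = 0.0432 to 0.0485). The count was 0 without each library in turn, P25 replicate 2 among them.

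Camera passed 9 lists although no gene passed, and none of the 9 passed with an estimated correlation. The interferon list had a mean log2 of 3.14 ± 0.569 at P29 and 4.04 ± 0.571 at P35. The macrophage list had 4.65 ± 0.614 and 5.60 ± 0.452, and the mast cell list 2.22 ± 0.570 and 3.29 ± 0.754. The basement membrane list was tighter, at 6.68 ± 0.00874 and 6.45 ± 0.0364. Interferon response genes rose: 0 of 19 genes, and 0 adjusted over the list alone. For interferon response genes camera gave adjusted p = 1.7e-12, adjusted p = 0.823 with an estimated correlation. It did so with a median log2 of 0.92. Macrophage and monocyte genes rose: 0 of 18 genes, and 0 adjusted over the list alone. For macrophage and monocyte genes camera gave adjusted p = 1.6e-10, adjusted p = 0.844 with an estimated correlation. It did so with a median of 0.93. Cytokines and chemokines rose: 0 of 19 genes, and 7 up adjusted over the list alone. For cytokines and chemokines genes camera gave adjusted p = 1.0e-10, adjusted p = 0.844 with an estimated correlation. It did so with a median of 0.95. Mast cell genes rose: 0 of 7 genes, and 0 adjusted over the list alone. For mast cell genes camera gave adjusted p = 0.000875, adjusted p = 0.844 with an estimated correlation. Basement membrane fell: 0 of 12 genes, and 4 down adjusted over the list alone. For basement membrane genes camera gave adjusted p = 4.6e-08, adjusted p = 0.314 with an estimated correlation. Oxidative phosphorylation fell: 0 of 30 genes, and 0 adjusted over the list alone. For oxidative phosphorylation genes camera gave adjusted p = 2.7e-05, adjusted p = 0.844 with an estimated correlation, ended without P29 replicate 1 at 0.229. Mature adipocyte genes fell: 0 of 23 genes, and 0 adjusted over the list alone. For mature adipocyte genes camera gave adjusted p = 0.00514, adjusted p = 0.844 with an estimated correlation, ended without P35 replicate 2 at 0.125. Insulin and glucose genes fell: 0 of 16 genes, and 0 adjusted over the list alone. For insulin and glucose handling genes camera gave adjusted p = 0.00729, adjusted p = 0.844 with an estimated correlation, ended without P35 replicate 2 at 0.0667. Immediate early genes rose: 0 of 19 genes, and 0 adjusted over the list alone. For immediate early and dissociation genes camera gave adjusted p = 0.0237, adjusted p = 0.844 with an estimated correlation, ended without P29 replicate 1 at 0.157 and P35 replicate 2 at 0.147 and P29 replicate 3 at 0.0846.

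From P35 to P49 single genes changed several-fold. Pon1 (ENSMUSG00000002588, chromosome 6, 5168090 to 5193946, GRCm38), a lipoprotein-associated esterase, rose from 8.91 ± 2.05 to 77.6 ± 16.1 FPKM (log2 2.99, adjusted p = 0.00207). Mest (ENSMUSG00000051855, chromosome 6, 30723547 to 30748455, GRCm38), an imprinted gene linked to fat cell enlargement, fell from 124 ± 11.2 to 14.2 ± 1.02 FPKM (log2 -3.03, adjusted p = 0.00338). The complement gene C7 rose from 3.19 ± 1.40 to 15.4 ± 2.54 FPKM (log2 2.01, adjusted p = 0.0471, but 0.179 without P49 replicate 1, the highest of 12 such libraries). Myoc rose from 1.06 ± 0.459 to 6.89 ± 1.003 FPKM (log2 1.95, adjusted p = 0.0322, but 0.171 without P49 replicate 1, the highest of 7 such libraries). The prostaglandin receptor Ptgfr rose from 4.82 ± 0.509 to 11.7 ± 2.62 FPKM (log2 1.10, adjusted p = 0.0034). Pcsk6 rose from 8.16 ± 0.624 to 18.5 ± 1.44 FPKM (log2 1.09, adjusted p = 0.00167). Atoh8 rose from 4.08 ± 0.418 to 8.68 ± 0.799 FPKM (log2 0.93, adjusted p = 0.00167). The growth factor Fgf2 rose from 5.76 ± 0.129 to 12.3 ± 1.30 FPKM (log2 0.97, adjusted p = 0.0112, but 0.0797 without P49 replicate 1, the highest of 4 such libraries). Gstt1 rose from 22.8 ± 0.983 to 41.5 ± 3.82 FPKM (log2 0.83, adjusted p = 0.0221, but 0.143 without P49 replicate 1, the highest of 6 such libraries). Fads1 rose from 10.9 ± 0.317 to 20.003 ± 0.995 FPKM (log2 0.82, adjusted p = 0.0236, but 0.143 without P49 replicate 1, the highest of 6 such libraries). Adrbk2 rose from 2.60 ± 0.497 to 5.23 ± 0.730 FPKM (log2 0.79, adjusted p = 0.0112, but 0.0805 without P49 replicate 1, the highest of 3 such libraries).

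Collagen and acute phase genes were among the falls. Col5a3 fell from 217 ± 23.2 to 90.6 ± 11.7 FPKM (log2 -1.25, adjusted p = 0.0112, but 0.0768 without P49 replicate 1, the highest of 3 such libraries). The elastin cross-linking gene Loxl1 fell from 50.7 ± 7.06 to 21.5 ± 4.33 FPKM (log2 -1.21, adjusted p = 0.0112, but 0.0797 without P49 replicate 1, the highest of 3 such libraries). The heme carrier Hpx fell from 6.37 ± 1.60 to 1.04 ± 0.293 FPKM (log2 -1.84, adjusted p = 0.00167). The endotoxin-binding Lbp fell from 81.4 ± 12.4 to 37.4 ± 1.77 FPKM (log2 -1.09, adjusted p = 0.0131, but 0.0805 without P49 replicate 1, the highest of 5 such libraries). Fmr1 fell from 146 ± 13.05 to 63.1 ± 1.72 FPKM (log2 -1.20, adjusted p = 0.0034). Adam12 fell from 7.85 ± 0.843 to 2.89 ± 0.0543 FPKM (log2 -1.18, adjusted p = 0.0034). Anxa8 fell from 60.9 ± 16.6 to 20.9 ± 0.667 FPKM (log2 -1.46, adjusted p = 0.0199, but 0.107 without P49 replicate 1, the highest of 5 such libraries). S100a8 fell from 12.9 ± 8.75 to 2.23 ± 0.849 FPKM (log2 -1.95, adjusted p = 0.0437, but 0.185 without P49 replicate 3, the highest of 12 such libraries). Klf14 fell from 5.81 ± 1.07 to 2.22 ± 0.0901 FPKM (log2 -1.07, adjusted p = 0.0112, but 0.0689 without P49 replicate 3, the highest of 3 such libraries). Basement membrane fell as a list: 3 down of 12 genes, and 5 down adjusted over the list alone. For basement membrane genes camera gave adjusted p = 1.4e-06, adjusted p = 0.314 with an estimated correlation. Col15a1 (from 199.9 ± 10.5 to 97.4 ± 8.08 FPKM, log2 -1.03) and Col4a2 (from 459.7 ± 6.53 to 266 ± 8.86 FPKM, log2 -0.79) led the list. Extracellular matrix fell: 2 down of 26 genes, and 4 down adjusted over the list alone. For extracellular matrix genes camera gave adjusted p = 0.00104, adjusted p = 0.844 with an estimated correlation. Clock genes rose: 0 of 17 genes, and 3 up adjusted over the list alone. For circadian clock genes camera gave adjusted p = 1.2e-06, adjusted p = 0.314 with an estimated correlation. The time of harvest is not labelled, so hour of day and age were not separated for these genes. Wnt targets rose: 0 of 6 genes, and 1 up adjusted over the list alone. For Wnt target genes camera gave adjusted p = 0.0114, adjusted p = 0.392 with an estimated correlation, ended with no filter at 0.204.

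Fatty acid synthesis rose: 1 up of 17 genes, and 2 up adjusted over the list alone. For fatty acid synthesis genes camera gave adjusted p = 0.0388, adjusted p = 0.844 with an estimated correlation, ended without each of 4 single libraries: P49 replicate 2 0.183, P35 replicate 3 0.144, P35 replicate 2 0.0824, P25 replicate 1 0.0538, and with median-ratio scaling at 0.0563. The replicate number as a block ended this call too. Cholesterol synthesis rose: 0 of 22 genes, and 2 up and 1 down adjusted over the list alone. For cholesterol synthesis genes camera gave adjusted p = 0.0162, adjusted p = 0.844 with an estimated correlation, ended without P35 replicate 3 at 0.395 and P49 replicate 2 at 0.0507. Insulin and glucose genes rose: 1 up of 16 genes, and 2 up adjusted over the list alone. For insulin and glucose handling genes camera gave adjusted p = 0.0172, adjusted p = 0.844 with an estimated correlation, ended without P35 replicate 2 at 0.12 and P49 replicate 3 at 0.0644, and with lists without shared members at 0.306. Members included Hk2 (from 54.3 ± 5.87 to 84.7 ± 1.43 FPKM, log2 0.64). Immediate early genes rose: 0 of 19 genes, and 0 adjusted over the list alone. For immediate early and dissociation genes camera gave adjusted p = 0.00899, adjusted p = 0.844 with an estimated correlation, ended without P35 replicate 1 at 0.0638. Oxidative phosphorylation fell: 0 of 30 genes, and 0 adjusted over the list alone. For oxidative phosphorylation genes camera gave adjusted p = 0.00307, adjusted p = 0.844 with an estimated correlation, ended without P35 replicate 1 at 0.0605. Cell proliferation fell: 0 of 21 genes, and 0 adjusted over the list alone. For cell proliferation genes camera gave adjusted p = 0.00865, adjusted p = 0.844 with an estimated correlation, ended without P35 replicate 2 at 0.137. Keratinocyte genes fell: 0 of 10 genes, and 0 adjusted over the list alone. For epidermal keratinocyte genes camera gave adjusted p = 0.0292, adjusted p = 0.844 with an estimated correlation, ended without P35 replicate 1 at 0.0716. Hair shaft genes fell: 0 of 7 genes, and 0 adjusted over the list alone. For hair shaft and inner root sheath genes camera gave adjusted p = 0.00675, adjusted p = 0.844 with an estimated correlation, ended without P35 replicate 3 at 0.0857. Mast cell genes fell: 0 of 7 genes, and 0 adjusted over the list alone. For mast cell genes camera gave adjusted p = 0.0114, adjusted p = 0.844 with an estimated correlation, ended without P35 replicate 2 at 0.117 and P49 replicate 3 at 0.0506. Erythroid genes fell: 0 of 5 genes, and 4 down adjusted over the list alone. For erythroid genes camera gave adjusted p = 0.0032, adjusted p = 0.844 with an estimated correlation. Interferon genes fell: 0 of 19 genes, and 0 adjusted over the list alone. For interferon response genes camera gave adjusted p = 0.0181, adjusted p = 0.844 with an estimated correlation, ended without P35 replicate 2 at 0.593 and P49 replicate 3 at 0.0619. Fatty acid oxidation did not pass: 1 down of 18 genes, and 1 down adjusted over the list alone. For fatty acid oxidation genes camera gave adjusted p = 0.0728. Members included Cpt1a (from 26.6 ± 3.39 to 14.2 ± 1.70 FPKM, log2 -0.86) down. Under the stromal covariate fatty acid synthesis (adjusted p = 0.23), cholesterol synthesis (0.058), insulin and glucose (0.0972), cell proliferation (0.0575), keratinocyte (0.0762) and interferon (0.183) genes no longer passed.

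In all, 69 genes passed between P35 and P49, 30 up and 39 down, and 1500 had an unadjusted p under 0.05. Without P25 replicate 2 the count was 341 with all 69 kept, and without P49 replicate 1 it was 13. The stromal covariate gave 748 and library weights 1119, with all 69 kept in both, and only the 2 ages 269 with 62 kept. C7 and Myoc did not pass with no filter (adjusted p = 0.0835 and 0.0551) or a pseudocount of 0.1 (0.164 and 0.094), nor S100a8 with no filter (0.0769), by voom (0.113) or with only the 2 ages (0.0754). Without P49 replicate 1 or replicate 3, 12 of the 20 genes named by the rule lost their call. Pon1, Ptgfr, Pcsk6, Atoh8, Mest, Hpx, Fmr1 and Adam12 kept theirs without each library in turn.

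**Figure D3:**
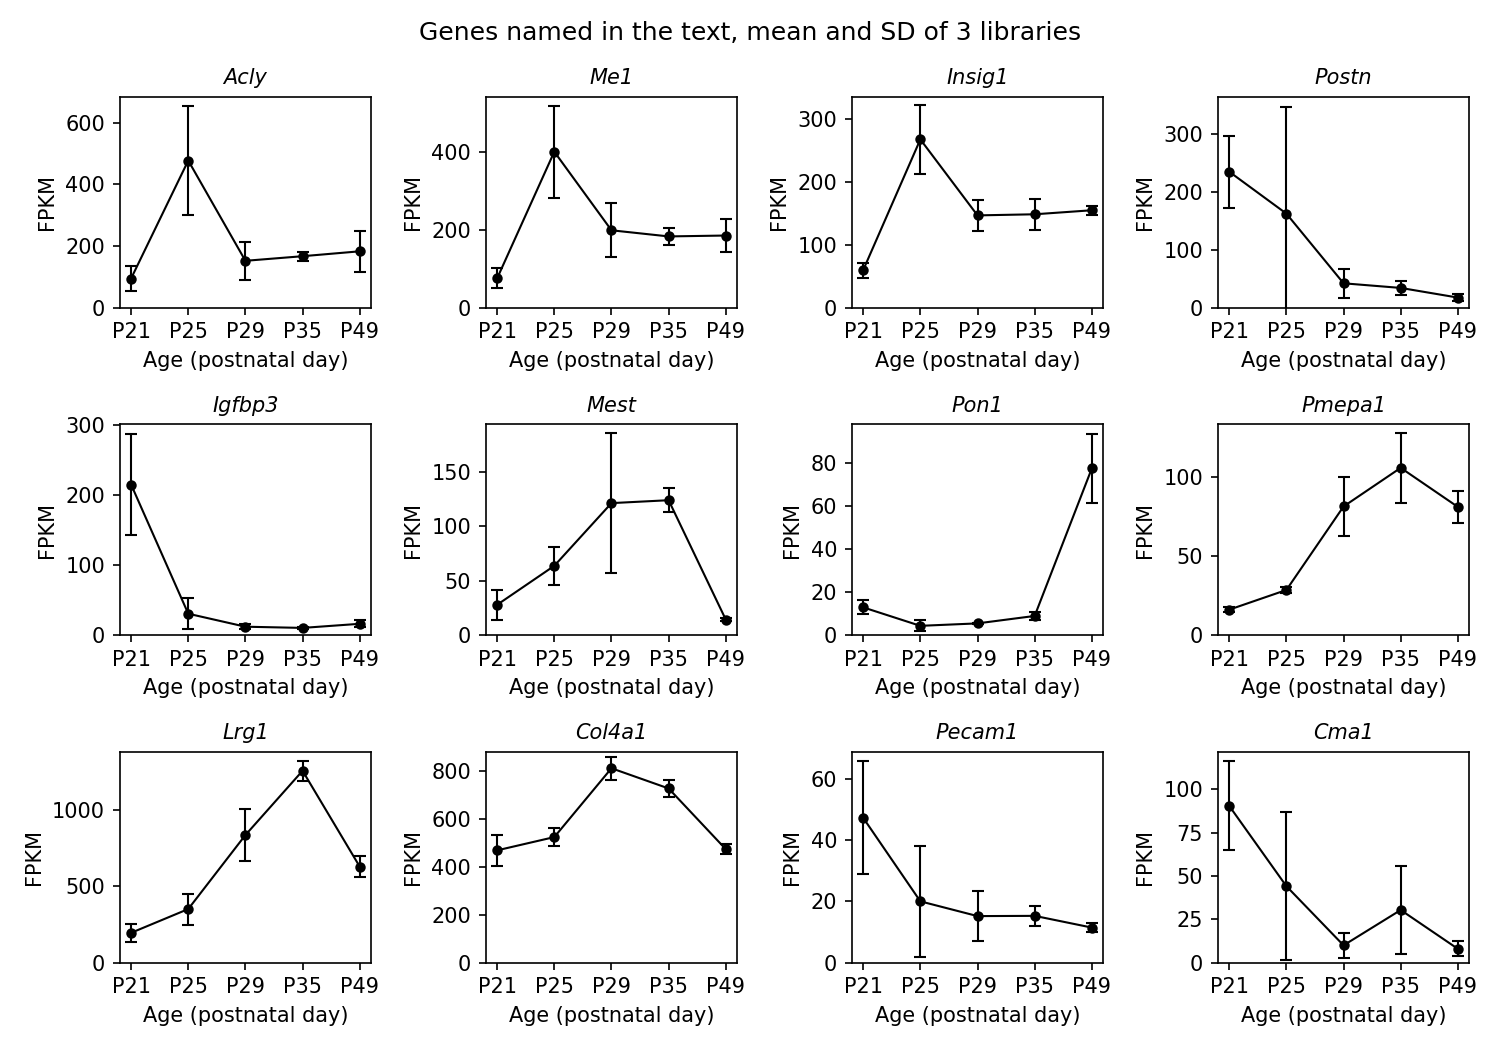
Mean and SD of 12 genes named in the text at the 5 ages, in FPKM, n = 3 libraries per age.

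Over the whole course, P49 against P21, Postn, Igfbp3 and H19 were among the largest falls, and C7, Cyp2e1 and Pon1 among the largest rises. Postn (ENSMUSG00000027750, chromosome 3, 54361109 to 54391034, GRCm38), a matrix protein of remodelling tissue, fell from 235 ± 62.4 to 17.3 ± 5.93 FPKM (log2 -3.71, adjusted p = 0.00329). Igfbp3 fell from 215 ± 72.5 to 16.1 ± 4.80 FPKM (log2 -3.64, adjusted p = 0.000198). H19 fell from 45.7 ± 16.1 to 2.66 ± 0.484 FPKM (log2 -3.62, adjusted p = 0.000968). Obsl1 (ENSMUSG00000026211, chromosome 1, 75479310 to 75506452, GRCm38), a cytoskeletal adaptor, fell from 17.3 ± 1.12 to 1.12 ± 0.225 FPKM (log2 -3.11, adjusted p = 9.7e-07). Pmepa1 rose from 16.1 ± 1.53 to 80.97 ± 10.1 FPKM (log2 2.26, adjusted p = 3.5e-05). The esterase Pon1 rose from 12.9 ± 3.31 to 77.6 ± 16.1 FPKM (log2 2.51, adjusted p = 0.0007). The complement gene C7 rose from 0.805 ± 0.184 to 15.4 ± 2.54 FPKM (log2 3.18, adjusted p = 0.000587). Cyp2e1, a monooxygenase, rose from 497 ± 62.5 to 2874 ± 156 FPKM (log2 2.53, adjusted p = 0.00254). Of the uncertain copies, Mup11 rose from 0.348 ± 0.201 to 18.1 ± 1.54 FPKM (log2 3.83, adjusted p = 5.1e-05). Mup7 rose from 0.842 ± 0.671 to 24.6 ± 6.14 FPKM (log2 3.83, adjusted p = 5.1e-05). Mup10 rose from 0.516 ± 0.272 to 15.7 ± 5.07 FPKM (log2 3.42, adjusted p = 5.0e-06). Mup3 rose from 1.64 ± 0.751 to 25.5 ± 4.64 FPKM (log2 3.36, adjusted p = 0.000148). Mup15 rose from 0.340 ± 0.352 to 12.2 ± 2.33 FPKM (log2 3.31, adjusted p = 9.8e-05). Orm1 rose from 31.2 ± 18.4 to 197 ± 10.7 FPKM (log2 2.86, adjusted p = 0.00124).

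Lipid lists were higher at P49. Fatty acid synthesis rose: 10 up of 17 genes, and 12 up adjusted over the list alone. For fatty acid synthesis genes camera gave adjusted p = 1.1e-07, adjusted p = 0.844 with an estimated correlation. Elovl6 (from 3.46 ± 1.11 to 19.8 ± 10.02 FPKM, log2 2.15) and Scd1 (from 2346 ± 844 to 8171 ± 347 FPKM, log2 1.86) led the list. Triglyceride synthesis rose: 5 up of 11 genes, and 7 up adjusted over the list alone. For triglyceride synthesis genes camera gave adjusted p = 0.000321, adjusted p = 0.844 with an estimated correlation. Dgat2 (from 268 ± 35.7 to 1018 ± 21.8 FPKM, log2 1.93) and Mogat1 (from 1.21 ± 0.0696 to 6.49 ± 0.575 FPKM, log2 1.76) led the list. Cholesterol synthesis rose: 9 up of 22 genes, and 13 up adjusted over the list alone. For cholesterol synthesis genes camera gave adjusted p = 2.6e-06, adjusted p = 0.844 with an estimated correlation. Mature adipocyte genes rose: 5 up and 1 down of 23 genes, and 6 up and 1 down adjusted over the list alone. For mature adipocyte genes camera gave adjusted p = 0.00039, adjusted p = 0.844 with an estimated correlation. Members included Tusc5 (from 56.8 ± 9.40 to 170.4 ± 9.87 FPKM, log2 1.58) and Cebpa (from 332 ± 27.7 to 599 ± 35.9 FPKM, log2 0.85) up and Aqp7 (from 66.98 ± 6.66 to 43.7 ± 5.26 FPKM, log2 -0.61) down. Fatty acid oxidation rose: 1 up of 18 genes, and 1 up adjusted over the list alone. For fatty acid oxidation genes camera gave adjusted p = 0.00478, adjusted p = 0.844 with an estimated correlation. Members included Cpt2 (from 32.3 ± 2.34 to 55.2 ± 1.19 FPKM, log2 0.76). Oxidative phosphorylation rose: 1 up of 30 genes, and 1 up adjusted over the list alone. For oxidative phosphorylation genes camera gave adjusted p = 0.0113, adjusted p = 0.844 with an estimated correlation, ended without P21 replicate 3 at 0.159, and with quantile normalization at 0.116. Hypoxia and glycolysis rose: 3 up and 1 down of 16 genes, and 4 up and 1 down adjusted over the list alone. For hypoxia and glycolysis genes camera gave adjusted p = 0.00504, adjusted p = 0.844 with an estimated correlation. Lipolysis did not pass: 3 up and 3 down of 16 genes, and 4 up and 3 down adjusted over the list alone. For lipolysis genes camera gave adjusted p = 0.256. Members included Plin1 (from 745 ± 59.6 to 1318 ± 71.5 FPKM, log2 0.82) up and Npr1 (from 8.72 ± 2.57 to 2.95 ± 0.459 FPKM, log2 -1.27) down. With the stromal index as a covariate, oxidative phosphorylation (adjusted p = 3.7e-05) and fatty acid oxidation (0.0274) passed in the other direction, as lower at P49. Mature adipocyte genes turned to down without passing (0.0866), and triglyceride synthesis (0.508) and hypoxia and glycolysis (0.114) no longer passed. The slope of the covariate comes from differences of the index within an age. These were widest at P25, where replicate 2 stood at 3.66 against 2.32 and 2.20. The reversals therefore lean on P25 replicate 2, and the covariate was not tried without it.

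Several matrix and stromal lists were lower at P49. Extracellular matrix fell: 19 down of 26 genes, and 22 down adjusted over the list alone. For extracellular matrix genes camera gave adjusted p = 3.4e-08, adjusted p = 0.844 with an estimated correlation. Members included Eln (from 129.6 ± 66.1 to 14.1 ± 3.29 FPKM, log2 -3.02). Basement membrane fell: 5 down of 12 genes, and 5 down adjusted over the list alone. For basement membrane genes camera gave adjusted p = 0.0388, adjusted p = 0.844 with an estimated correlation, ended without each of 4 single libraries: P21 replicate 2 0.173, P49 replicate 1 0.0818, P21 replicate 1 0.0609, P25 replicate 2 0.0528, and with median-ratio scaling at 0.07. Endothelial genes fell: 13 down of 15 genes, and 15 down adjusted over the list alone. For endothelial genes camera gave adjusted p = 2.7e-05, adjusted p = 0.844 with an estimated correlation. Members included Pecam1 (from 47.3 ± 18.5 to 11.4 ± 1.58 FPKM, log2 -1.90). Preadipocyte and fibroblast genes fell: 7 down of 17 genes, and 1 up and 10 down adjusted over the list alone. For preadipocyte and fibroblast genes camera gave adjusted p = 0.00478, adjusted p = 0.844 with an estimated correlation. Members included Thy1 (from 40.3 ± 9.01 to 7.21 ± 1.77 FPKM, log2 -2.33) and Lum (from 76.5 ± 22.3 to 15.8 ± 4.85 FPKM, log2 -2.20). Mast cell genes fell: 7 down of 7 genes, and 7 down adjusted over the list alone. For mast cell genes camera gave adjusted p = 6.5e-05, adjusted p = 0.844 with an estimated correlation. Members included Cma1 from 90.4 ± 25.7 to 7.92 ± 4.32 FPKM (log2 -3.42, adjusted p = 0.00742). Cpa3 fell from 61.1 ± 19.3 to 5.11 ± 2.56 FPKM (log2 -3.38, adjusted p = 0.00504). Mcpt4 fell from 132 ± 46.4 to 13.5 ± 6.18 FPKM (log2 -3.22, adjusted p = 0.00774). Tpsb2 fell from 80.7 ± 22.5 to 8.53 ± 4.42 FPKM (log2 -3.16, adjusted p = 0.00839). Erythroid genes fell: 5 down of 5 genes, and 5 down adjusted over the list alone. For erythroid genes camera gave adjusted p = 2.6e-05, adjusted p = 0.772 with an estimated correlation. Members included the uncertain copies Hbb-bs from 125 ± 30.9 to 13.3 ± 6.39 FPKM (log2 -3.24, adjusted p = 0.00108). Hba-a1 fell from 106 ± 26.0 to 11.7 ± 5.76 FPKM (log2 -3.18, adjusted p = 0.000791). Cell proliferation fell: 1 down of 21 genes, and 0 adjusted over the list alone. For cell proliferation genes camera gave adjusted p = 0.00288, adjusted p = 0.844 with an estimated correlation. Immediate early genes fell: 3 down of 19 genes, and 5 down adjusted over the list alone. For immediate early and dissociation genes camera gave adjusted p = 0.00307, adjusted p = 0.844 with an estimated correlation. Endoplasmic reticulum stress genes fell: 2 down of 16 genes, and 2 down adjusted over the list alone. For endoplasmic reticulum stress genes camera gave adjusted p = 0.0181, adjusted p = 0.844 with an estimated correlation. The macrophage (adjusted p = 0.79), pericyte (0.0643), nerve (0.413), lymphocyte (0.0632), skeletal muscle (0.0535), keratinocyte (0.256), dermal papilla (0.0767), hair shaft (0.763) and melanocyte (0.961) lists did not pass. In these, Cspg4 (from 9.96 ± 2.22 to 35.8 ± 1.19 FPKM, log2 1.77) and Pmp22 (from 144 ± 15.1 to 211 ± 8.46 FPKM, log2 0.55) rose, unlike the means of their lists. The pericyte list had a mean log2 of 3.19 ± 0.352 at P21 and 2.22 ± 0.180 at P49. The nerve list had 3.20 ± 0.409 and 2.54 ± 0.126. With the stromal covariate, cell proliferation (adjusted p = 0.0254) and immediate early genes (0.0145) passed in the other direction, as higher at P49. These reversals too lean on P25 replicate 2. The endothelial (0.525) and preadipocyte (0.111) lists turned to up without passing. The extracellular matrix (0.303), basement membrane (0.102) and endoplasmic reticulum stress (0.804) lists no longer passed.

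Interferon genes were higher at P49: 7 up of 19 genes, and 8 up adjusted over the list alone. For interferon response genes camera gave adjusted p = 9.9e-06, adjusted p = 0.844 with an estimated correlation. Ifit1 (from 7.65 ± 2.34 to 37.9 ± 6.49 FPKM, log2 2.19) and Ifit2 (from 4.09 ± 0.869 to 20.1 ± 2.75 FPKM, log2 2.05) led the list. Cytokines and chemokines rose: 6 up and 1 down of 19 genes, and 6 up and 1 down adjusted over the list alone. For cytokines and chemokines genes camera gave adjusted p = 0.0478, adjusted p = 0.844 with an estimated correlation, ended without each of 7 single libraries: P49 replicate 1 0.107, P21 replicate 2 0.0805, P21 replicate 3 0.0602, P49 replicate 2 0.0596, P29 replicate 1 0.054, P35 replicate 2 0.0507, P25 replicate 1 0.0504, and with quantile normalization at 0.222 and median-ratio scaling at 0.131. Members included Ccl4 (from 40.7 ± 14.9 to 174 ± 35.03 FPKM, log2 2.11) and Ccl5 (from 1.57 ± 1.14 to 9.61 ± 0.653 FPKM, log2 2.13) up and Cxcl12 (from 46.3 ± 15.2 to 10.97 ± 3.46 FPKM, log2 -1.97) down. Clock genes rose as a list: 8 up and 2 down of 17 genes, and 9 up and 2 down adjusted over the list alone. For circadian clock genes camera gave adjusted p = 0.00729, adjusted p = 0.772 with an estimated correlation. Members included Dbp (from 24.9 ± 0.263 to 102 ± 15.1 FPKM, log2 1.98) up and Arntl (from 2.64 ± 0.465 to 0.820 ± 0.151 FPKM, log2 -0.997) down. Hour of day and age were again not separated, since the time of harvest is not labelled. Hair cycle signals fell: 2 up and 8 down of 24 genes, and 2 up and 11 down adjusted over the list alone. For secreted hair cycle signals camera gave adjusted p = 0.0313, adjusted p = 0.844 with an estimated correlation, ended without P49 replicate 3 at 0.0644 and P21 replicate 1 at 0.0609 and P49 replicate 1 at 0.0522. Members included Fgf2 (from 5.99 ± 0.906 to 12.3 ± 1.30 FPKM, log2 0.93) up and Dkk3 (from 6.77 ± 3.76 to 0.641 ± 0.156 FPKM, log2 -2.13) and Bmper (from 5.92 ± 1.59 to 1.10 ± 0.182 FPKM, log2 -1.70) down. Wnt targets did not pass: 2 up and 1 down of 6 genes, and 4 up and 1 down adjusted over the list alone. For Wnt target genes camera gave adjusted p = 0.0632. Members included Axin2 (from 2.31 ± 0.415 to 4.80 ± 0.0346 FPKM, log2 0.82) up. Under the stromal covariate the hair cycle signals turned to up without passing (adjusted p = 0.535).

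In all, 2679 genes passed between P21 and P49, 1021 up and 1658 down. Of these, 616 changed at least 2-fold on the scale of FPKM + 1. All 20 genes named by the rule kept their call without each library in turn. Without P25 replicate 2 the count was 4421, with 2652 of the 2679 kept, and without P21 replicate 1 it was 1058. Quantile normalization gave 1422 up and 1221 down, and median-ratio scaling 1398 up and 1148 down, so the larger number of falls depended on scaling. Library weights gave 5142 and only the 2 ages 4154. With the stromal index as a covariate 1658 genes passed and 658 of the 2679 were kept, and of the 20 named genes Cma1, Cpa3, Mcpt4 and Tpsb2 lost their call (adjusted p = 0.0768 to 0.157). The stromal index was lower in each P49 library (2.08 to 2.47) than in each P21 library (3.22 to 3.96), so changes within adipocytes and changes in the cells present were not separated.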

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

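Median-ratio scaling, the stromal covariate, library weights and voom were chosen after the data were seen, and the count-only alternatives planned for a file of counts were not run. Leaving out 1 library at a time gave 1417 to 6378 genes over the 5 ages, 810 to 5545 for P25 against P21, 8 to 77 for P29 against P25, 0 for P35 against P29, 13 to 341 for P49 against P35, 1058 to 4421 for P49 against P21 and 67 to 88 list calls. Of 75 list calls, 39 were kept without each library in turn. With only the 2 ages compared the counts were 0, 3, 269 and 4154 for P25 against P21, P29 against P25, P49 against P35 and P49 against P21. A 2-fold minimum on the scale of FPKM + 1, which by construction lowers a count, left 817, 351, 18, 21 and 616 genes (5 ages and the 4 comparisons with calls). For the 5 ages it was taken on the largest difference from P21. Library weights gave 7383 genes over the 5 ages, and 5924, 154, 1119 and 5142 in those comparisons. P25 replicate 2 had the lowest weight, 0.0994. The stromal covariate gave 294, 30, 748 and 1658 for P29 against P25, P35 against P29, P49 against P35 and P49 against P21. For P29 against P25, no filter gave 27, the replicate block 31 and voom 29, and no filter gave 2 for P35 against P29. An estimated correlation gave 0 list calls and fry 17, with 16 of the 75 kept. P21 held the highest mean for 46.2% of the genes called over the 5 ages, and for 33.6% after quantile normalization. It did so for 55% of called genes whose highest and lowest age means lay at least 2-fold apart, another set than the 817. PC1 held 54.3% over all genes tested.

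List tests that reversed under the stromal covariate were, at P25 against P21, mature adipocyte (adjusted p = 0.696), fatty acid oxidation (0.152), preadipocyte (0.253) and macrophage (0.645). At P49 against P21 they were mature adipocyte (0.0866), fatty acid oxidation (0.0274), oxidative phosphorylation (3.7e-05), preadipocyte (0.111), cell proliferation (0.0254), endothelial (0.525), immediate early (0.0145) and hair cycle signals (0.535). The index holds the endothelial list itself, so the loss of that list's call is built in, though the change of sign is not. Without P25 replicate 2, extracellular matrix (0.0336) and immediate early genes (0.00122) reversed at P29 against P25, within leave-one-out ranges of 0.000124 to 0.141 and 0.000282 to 0.173. For the other changes the cause was not tested. The same-numbered pairs behind the replicate block correlated at -0.60 to 0.74. For P25 with P29 and P29 with P35 all 3 pairs lay above 0.1 (0.29, 0.74 and 0.47, and 0.40, 0.61 and 0.25), but P25 replicate 1 correlated more with P29 replicate 3 (0.56) than with its own number. Under the block fatty acid synthesis at P49 against P35 reached 0.0519, and 0 other list calls changed. Quantile normalization and median-ratio scaling each ended 5 list calls, and no filter and lists without shared members 2 each.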

Other observations

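The gene groups of the first paragraphs, the swap test, the list form of the wrong-label test and the check of its gene form on left-out P21 libraries, the fixed-ratio test on P49 and the genes named in this part were chosen only after the result was seen. The camera p-values of the gene groups, adjusted over these groups alone, therefore do not test the patterns independently. Several imprinted genes fell early, both some that favour and some that restrain growth: H19 averaged 45.7 ± 16.1, 8.61 ± 8.33, 2.996 ± 1.47, 3.63 ± 1.91, 2.66 ± 0.484 FPKM at the 5 ages, Igf2 12.96 ± 4.16, 2.76 ± 2.43, 0.816 ± 0.549, 0.615 ± 0.246, 0.791 ± 0.108, Peg3 68.3 ± 5.99, 24.5 ± 8.11, 25.8 ± 4.70, 23.9 ± 1.55, 27.8 ± 5.14 and Zim1 15.3 ± 2.51, 4.47 ± 3.04, 2.84 ± 0.756, 1.85 ± 0.102, 1.48 ± 0.528. Of 23 tested imprinted genes 2 were higher and 8 lower at P25 than at P21 (camera adjusted p = 0.0183, 0.27 with an estimated correlation, 0.0994 with the stromal covariate), and 2 were higher and 13 lower at P49 than at P21 (camera adjusted p = 0.000158, 0.139 with an estimated correlation). Mest and Klf14 went another way, with Mest at 27.8 ± 13.8, 63.5 ± 17.6, 121 ± 64.0, 124 ± 11.2, 14.2 ± 1.02 FPKM and Klf14 at 1.31 ± 0.349, 4.14 ± 1.09, 5.40 ± 0.818, 5.81 ± 1.07, 2.22 ± 0.0901.

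Most acute phase genes had their highest mean at P35. Lrg1 averaged 195 ± 59.1, 351 ± 101, 836 ± 172, 1257 ± 66.96, 629 ± 69.8 FPKM at the 5 ages, Hp 5099 ± 1957, 4057 ± 1403, 7933 ± 1195, 10344 ± 408, 6282 ± 463 and Hpx 0.618 ± 0.242, 3.11 ± 0.890, 5.45 ± 0.993, 6.37 ± 1.60, 1.04 ± 0.293. Of 13 tested acute phase genes, 8 had their highest mean at P35 and all 8 differed over the 5 ages, while 3 were highest at P49, 1 at P29 and 1 at P21. Camera passed the group as higher at each step to P35. The adjusted p was 0.00533 (0.27 with an estimated correlation) for P25 against P21. It was 8.0e-06 (0.139) for P29 against P25 and 0.00062 (0.218) for P35 against P29. At P49 against P35 camera passed the group as lower (adjusted p = 4.1e-05, 0.139 with an estimated correlation). Singly, limma passed 4 of the 13 as higher at P25, 2 at P29 (0 by voom, and 0 without P25 replicate 2) and 0 at P35 (3 at an unadjusted p under 0.05, 0 by voom). At P49 against P35 it passed 2 as lower, and 4 without P25 replicate 2. Genes encoded in the mitochondrion held 3.82 ± 0.344 percent of reads at P21, 7.15 ± 1.20 at P25, 8.23 ± 0.867 at P29, 8.91 ± 1.30 at P35 and 6.53 ± 0.753 at P49. Of these 13 genes, 10 were higher at P25 than at P21 (camera adjusted p = 1.4e-10, 0.139 with an estimated correlation).

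P25 replicate 2 lay with the P21 libraries on the first 2 principal components, but apart from them on the third. A swap with a P21 library was argued against, since 0 of the 3 P21 libraries lay nearer to P25 replicates 1 and 3. The nearest, P21 replicate 2, had a mean r of 0.956 to these and 0.985 to the other P21 libraries. Exchanging it with P25 replicate 2 nevertheless called 3069 genes for P25 against P21, more than the 2312 of the real labels. A P21 sample under the wrong label was not excluded. Of 3440 genes that separate the ages, 48.4% put P25 replicate 2 beyond the P21 range toward the later ages, past the bound of 25% set before. That bound was too low, since measured the same way against the other P21 pair 2 of the 3 left-out P21 libraries passed it too. The left-out P21 replicates 1, 2 and 3 reached 24.5%, 70.3% and 36.4%, where this library reached 53.0%, 56.2% and 51.8%. By the share of these genes within the range of the later libraries they reached 9.97%, 28.3% and 14.8%, and this library 36.1%, 32.0% and 32.7%, higher in all 3 pairs. That goes against a P21 sample, but the mean of 33.6% lay below 65.0%, the upper end of the 95% prediction interval of the left-out P21 libraries (17.7 ± 9.53%, n = 3). P25 replicate 2 lay beyond the 95% prediction interval of the P21 libraries in 6 of 36 lists, with 1.8 expected; a first, binomial form of this test gave p = 0.00834, but the lists are correlated, and a simulation with their covariance, set up after that value was known, gave p = 0.0754. Of the 6, hair shaft genes (mean log2 3.97, against 0.107 ± 0.0164 at P21 and 0.487 and 2.29 in P25 replicates 1 and 3) and cholesterol synthesis (mean log2 4.14, against 3.23 ± 0.124 at P21 and 4.13 and 4.496 in P25 replicates 1 and 3) lay toward the other P25 libraries, as did the sum of Mup genes (14.998 FPKM, against 3.64 to 7.04 at P21 and 23.1 and 31.4), and these go against a P21 sample. Insulin and glucose, cell proliferation, interferon and sex-linked genes lay beyond the interval without lying toward the other P25 libraries. The single lists were picked after their values were seen, and hair genes near 0 in all P21 libraries give no measure of how early a P21 animal may start hair growth. A lower share of adipocytes with other cells in a fixed ratio was argued against only weakly, by a range of 2.23 log2 units between their medians. A Kruskal-Wallis test of whether their lists differed gave a permutation p = 1e-04, the smallest 10000 resamples can give. The permutation treats genes as independent, and the range comes from 1 library against 2. A wrong label, other cells in other proportions, hair follicle pieces and the animal's own stage may each remain.

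Markers of several other cells were lower at P49 than at P21. A fixed ratio of other cells was argued against by a range of 3.17 log2 units between list medians. These ran from -3.16 for mast cells to 0.01 for melanocytes. The Kruskal-Wallis test between the lists gave a permutation p = 1e-04, the smallest possible. With genes averaging at least 5 FPKM and a pseudocount of 0.1, the range over 8 lists was 3.23. The permutation treats genes as independent, though markers of 1 cell type may move together. Its p therefore does not measure the spread between libraries. Scaling was argued against, with 10 of 13 endothelial calls kept under median-ratio scaling. Yam1, which overlaps an rRNA gene on the other strand, changed the share of reads left to other genes by 0.0188 log2, against an endothelial median of -1.48. A change of cells with age, or in how well the fat cells separated from other cells at each age, may remain, and neither was tested.

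Of 21 Mup genes 8 were tested, and 7 of these were higher at P49 than at P21. Liver RNA was argued against by a median of 0.0476 FPKM for 7 abundant liver transcripts at P49, against 13.9 for the tested Mup genes. Alb was the exception at 36.4 FPKM, above each Mup gene, but it fell from 79.8 at P21 (adjusted p = 0.0203) while the Mup genes rose, and the other 6 stayed at or below 0.869 FPKM. Reads moving between near-identical copies were argued against by the sum over 21 Mup genes, which was 21.2 times as high at P49. Expression in the adipocytes at the later ages may remain as a hypothesis.

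Other splits of the same libraries were counted. Over the 5 ages, only 1 of 100 splits, the real one, reached 3224 genes. That makes a chance split of these libraries unlikely but does not exclude it. The highest other split, a random one, still called 1996 genes. For 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real and highest other counts, with the number of splits as large, the real one included, were 2312 and 3069 (2 splits) for P25 against P21, 49 and 0 (1) for P29 against P25, 0 and 7 (10) for P35 against P29, 69 and 0 (1) for P49 against P35, and 2679 and 0 (1) for P49 against P21. The split with 3069 genes exchanged P21 replicate 2 with P25 replicate 2. Exchanging P25 replicate 2 with P21 replicate 1 or with P21 replicate 3 called 0 and 1 genes. The place of P25 replicate 2 among the P21 libraries therefore does not by itself account for that count.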
